A study of Homo sapiens with 8 samples.

How the data were processed

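RNA sequencing libraries were analysed from HK2 cells, an immortalised human renal proximal tubular epithelial line. All 8 libraries came from cells kept for 24 h in hypoxia and then 4 h in reoxygenation, per the labels. Of these, 4 came from cells overexpressing DEF6 (DEF6-OE) and 4 from wild-type control cells (Control), and the group and replicate number of each library were taken from its title. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. The labels record no sequencing or culture batch.

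The deposited table of normalized counts (unit: signal) was made by the authors. Its values have the form of gene counts divided by a size factor for each library. In every library, 100% of values were whole multiples of the smallest value above 0, within 1e-06, and whole reads were recovered by dividing by that step. The recovered totals ran from 18741374 to 20732815 reads in DEF6-OE and from 19130628 to 21998627 in Control. A second deposited table holds FPKM values by the authors, in which fragments are scaled by gene length and library size. Names that occur more than once in the FPKM table were left out of every use of it. The submitters' processing notes name Bowtie2, RSEM 1.3.1, DESeq2 1.4.5 and the build hg38, per the labels. The roles of these tools, the gene annotation, the library kit and any strand setting are not given in the sources used here. Reads of overlapping or antisense genes and of near-identical copies could therefore have been split in ways that cannot be checked. Of the 15983 gene names in the table of normalized counts, 15739 were found in GENCODE 29, from which all coordinates are given (GRCh38, the assembly also called hg38).

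Genes with a mean normalized count of at least 10 over the 8 libraries were kept, which left 13158 genes. The values were taken as log2(normalized count + 1) and fitted with limma 3.58.1 in R 4.3.3 (eBayes with trend and robust), DEF6-OE against Control, two-sided, with Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p under 0.05. Fold changes are on the log2(normalized count + 1) scale, which understates the change of low genes. Values are given as means ± SD of normalized counts (n = 4 per group), and log2 fold changes with their standard errors. DEF6, WWP2 and PARP1 were also tested by an exact two-sided permutation test over the 70 assignments of libraries to groups, whose smallest p is 0.0286. Ratios of pooled reads carry exact binomial 95% intervals, which cover counting error only.

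Before the data were examined, 32 gene lists were fixed. The 30 lists with at least 5 tested members were tested with camera (limma, inter-gene correlation preset at 0.01, two-sided), adjusted over the lists. Camera with an estimated correlation and fry were run beside it. The results of some gene groups and genes are not reported here. Named genes follow a rule fixed at the same time. It takes DEF6, WWP2 and PARP1, then the 12 called genes with the largest increase and the 12 with the largest decrease among those with a mean of at least 50 and groups that do not overlap, leaving out DEF6 and unnamed loci. It then takes up to 4 called members per list with the largest absolute log2 fold change. Further list members, and genes outside the lists in the closing section, were chosen after their values were seen.

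Alternatives fixed before the data were examined were pseudocounts of 0.5 and 10, no filter, a minimum mean of 50, equal library totals, quantile normalization and the FPKM table (pseudocount 0.1, mean FPKM of at least 0.5). The others were a replicate block, eBayes with neither trend nor robust, array weights, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, and each library left out in turn. One alternative was chosen after seeing the data: it keeps only genes whose ratio of normalized count to FPKM, an index of the effective length that the authors' quantification gave the gene, was stable over the 8 libraries (SD under 0.2 and group shift under 0.2 on the log2 scale).

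The scripts were tested on simulated counts for DEF6-OE against Control over 13093 genes, with 200 genes changed. The limma test recovered 8% of genes changed 1.25-fold, 50% at 1.5-fold, 76% at 2-fold and 94% at 4-fold, and 2.44% of its calls were false. The edgeR test recovered the same percentages with 3.23% false calls. The simulation changed 200 genes and a list of 20, far fewer than the 2160 called in the data. Recovery and false calls after adjustment depend on the share of changed genes, so these percentages need not hold for the data. In the same simulation 31 unchanged genes, 18.0% of the DESeq2 calls, were false, against an adjusted p threshold of 0.05. DESeq2 therefore did not pass the limit set for all tools at first, the limit was then applied to limma and edgeR only, and DESeq2 is given only as an alternative. Camera called the simulated list of 20 shifted genes, and 4 of 200 lists without a shift fell under its unadjusted threshold. The simulated genes were drawn independently, so this did not test camera on lists whose members move together. In the data the estimated correlation of the called lists ran from -0.07 (fibroblast markers) to 0.29 (mitosis), against the preset of 0.01. For the fibroblast and ATF4 lists (-0.07 and -0.03) it lay below the preset. Their loss with an estimated correlation is therefore not explained by members that move together. Pairs of libraries within a group differed by 15.7 to 27.4 times the counting noise (chi-square per degree of freedom), so no library was counted as a duplicate.

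Single-library jumps were counted as genes for which 1 library lay at least 1 on the log2 scale from the other 3 of its group, which spanned at most 0.5, with a highest count of at least 200. The number of outlying libraries in groups of 4 was counted with Dixon's test (critical value 0.829).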

Results

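RNA was sequenced from HK2 cells, a cultured line of human renal tubular epithelium, after 24 h of hypoxia and 4 h of reoxygenation, a cell model of ischaemia and reperfusion. The series compared 4 libraries from cells overexpressing DEF6 with 4 libraries from wild-type control cells. Its title names DEF6, the ubiquitin ligase WWP2 and PARP1, the main poly(ADP-ribose) polymerase of the DNA damage response, in renal ischaemia reperfusion injury. No library without hypoxia was part of the comparison, so every value below describes cells after reoxygenation. Any other difference between the DEF6-OE and the wild-type cells cannot be told apart from DEF6, for every gene and list below. The recovered reads per library ran from 18741374 to 20732815 in DEF6-OE and from 19130628 to 21998627 in Control.

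DEF6, a guanine nucleotide exchange factor known mainly from lymphocytes, was almost silent in Control cells and abundant in DEF6-OE cells. It had 13657 ± 835 normalized counts in DEF6-OE (SD, n = 4) and 3.15 ± 0.327 in Control (SD, n = 4). The log2 fold change was 11.69 ± 0.08 (SE, limma adjusted p = 4.21e-11). The 4 Control libraries together held 13 DEF6 reads against 53863 in DEF6-OE, a ratio of 4321 with a 95% counting interval from 2527 to 8116. In the exact permutation test of the 3 title genes, DEF6 had p = 0.0286, the smallest this design can give. Gene-level counts do not separate the cells' own DEF6 transcript from the introduced one. DEF6 lies on chromosome 6 from 35297852 to 35321771 on the plus strand (GENCODE 29, GRCh38).

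WWP2 and PARP1 transcripts did not pass the test. WWP2 (chromosome 16, 69762306 to 69941741) had 1110 ± 190 normalized counts in DEF6-OE and 1006 ± 69.7 in Control (SD, n = 4 each), a log2 fold change of 0.13 with a 95% interval from -0.13 to 0.39 (limma adjusted p = 0.467). DEF6-OE replicate 2 alone reached 1394, and without it the WWP2 difference was 0.02. PARP1 (chromosome 1, 226360691 to 226408079) had 6074 ± 120 and 5842 ± 168 normalized counts, a log2 fold change of 0.06 with a 95% interval from -0.01 to 0.13 (limma adjusted p = 0.246). The exact permutation p was 0.429 for WWP2 and 0.0857 for PARP1. These are transcript levels, and neither protein nor ubiquitination was measured here.

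**Figure D1:**
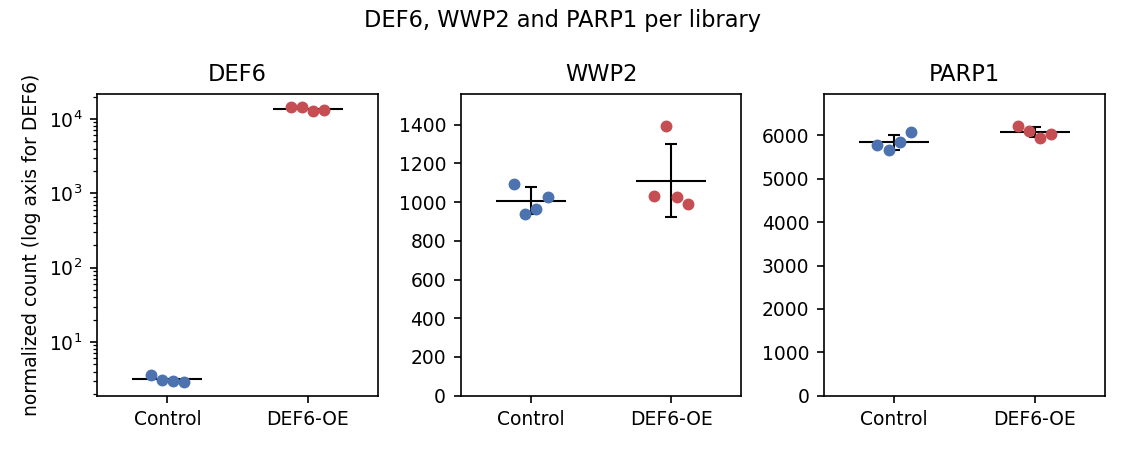
Normalized counts of DEF6 (log axis), WWP2 and PARP1 (linear axes from 0) in each library, with the group mean as a line and, for WWP2 and PARP1, the SD as bars. DEF6 is at 12721 or more in all 4 DEF6-OE libraries and at 3.61 or less in all 4 Control libraries, while the groups overlap for WWP2 and PARP1.

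Beyond DEF6, 5 gene lists passed camera as higher in DEF6-OE (NF-kB targets, TGF-beta targets and matrix, fibroblast markers, mitosis and ATF4 targets) and 1 as lower (cholesterol synthesis), each with a part of its members called. With an estimated correlation 0 of these 6 lists passed (adjusted p = 0.0732 to 0.235), and 7 of the 35 splits of the 8 libraries into 4 and 4, the real one included, gave as many lists, the other 6 of them with 3 libraries of each group kept together. Of 13158 genes tested, 2160 (16.4%) were called, 1152 higher and 1008 lower in DEF6-OE. Most changes were small: the median absolute log2 fold change of called genes was 0.33, and 138 genes changed at least 2-fold, 90 higher and 48 lower. The groups did not overlap for 26.1% of tested genes, against 2.86% by chance. The number of called genes was 1346 without DEF6-OE replicate 2, 1409 without Control replicate 1, 1407 without Control replicate 2, 1353 without Control replicate 4 and 946 in the FPKM table. The 2-fold count was 61 in the FPKM table, 83 with a pseudocount of 10 and 56 at a minimum mean of 50.

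The 12 named genes with the largest increases were FSTL1, DCN, SCG2, TLL2, CLEC4E, FAT2, COL8A1, KCNIP1, GDNF, THBS2, EDIL3 and RBM38. FSTL1, a secreted follistatin-like glycoprotein, rose from 16.3 ± 5.18 to 99.7 ± 4.10 normalized counts, a log2 fold change of 2.59 ± 0.21 (SE, limma adjusted p = 0.000438). The proteoglycan gene DCN, the granin gene SCG2 and the tolloid-like protease gene TLL2 (chromosome 10, 96364606 to 96513918) followed with 2.54, 2.36 and 2.22. CLEC4E, a C-type lectin receptor of innate immunity, rose from 259 ± 28.5 to 979 ± 150, a log2 fold change of 1.91 ± 0.12 (SE, limma adjusted p = 0.00019). FAT2, an atypical cadherin, rose by 1.80 and KCNIP1, a potassium channel subunit, by 1.69. GDNF, a growth factor of ureteric bud development, rose by 1.55. The matrix genes THBS2 and EDIL3, at means of 950 ± 29.1 and 1243 ± 94.9 in DEF6-OE, rose by 1.45 ± 0.04 and 1.44 ± 0.08 (SE), although the THBS2 value was 0.72 in the FPKM table. COL8A1 rose by 1.78, against 1.11 in the FPKM table, and RBM38 by 1.44, but COL8A1 passed the threshold only without Control replicate 1 or 2 when libraries were left out in turn, and RBM38 only without Control replicate 3, with adjusted p otherwise up to 0.0695 and 0.0874.

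The 12 named genes with the largest decreases were JRK, DTX4, TMEM246, FRS2, LRCH2, ZNF793, VWA1, RAD54B, DHRS9, DPP4, CLIP3 and MAGIX. The most abundant was DPP4, a peptidase of the proximal tubule brush border (chromosome 2, 161992241 to 162074542). It fell from 4995 ± 84.9 to 2272 ± 177 normalized counts, a log2 fold change of -1.14 ± 0.06 (SE, limma adjusted p = 4.72e-05). TMEM246 had a log2 fold change of -1.57 ± 0.13, LRCH2 of -1.36 ± 0.20 and the retinol dehydrogenase family gene DHRS9 of -1.15 ± 0.11 (SE). JRK, at -2.18, and ZNF793, at -1.36, differed between the tables. In the FPKM table their log2 fold changes were -0.75 (limma adjusted p = 0.192) and -0.16 (adjusted p = 0.791). CLIP3 also lost its call there, with a log2 fold change of -1.17 against -1.09 (adjusted p = 0.0865). DTX4, FRS2 and MAGIX lost theirs at smaller values, -0.73 against -1.67, -0.21 against -1.46 and -0.31 against -1.08 (adjusted p = 0.108, 0.512 and 0.396). RAD54B had a log2 fold change of -1.17, against -0.72 in the FPKM table (adjusted p = 0.0259), and VWA1 of -1.18. With libraries left out in turn, RAD54B and FRS2 passed only without DEF6-OE replicate 4 (adjusted p otherwise up to 0.0966 and 0.094). VWA1 missed the threshold without DEF6-OE replicates 2 or 3 or Control replicates 1 or 2 (up to 0.0627), and DTX4 without DEF6-OE replicate 2 or Control replicate 2 (up to 0.0535).

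**Figure D2:**
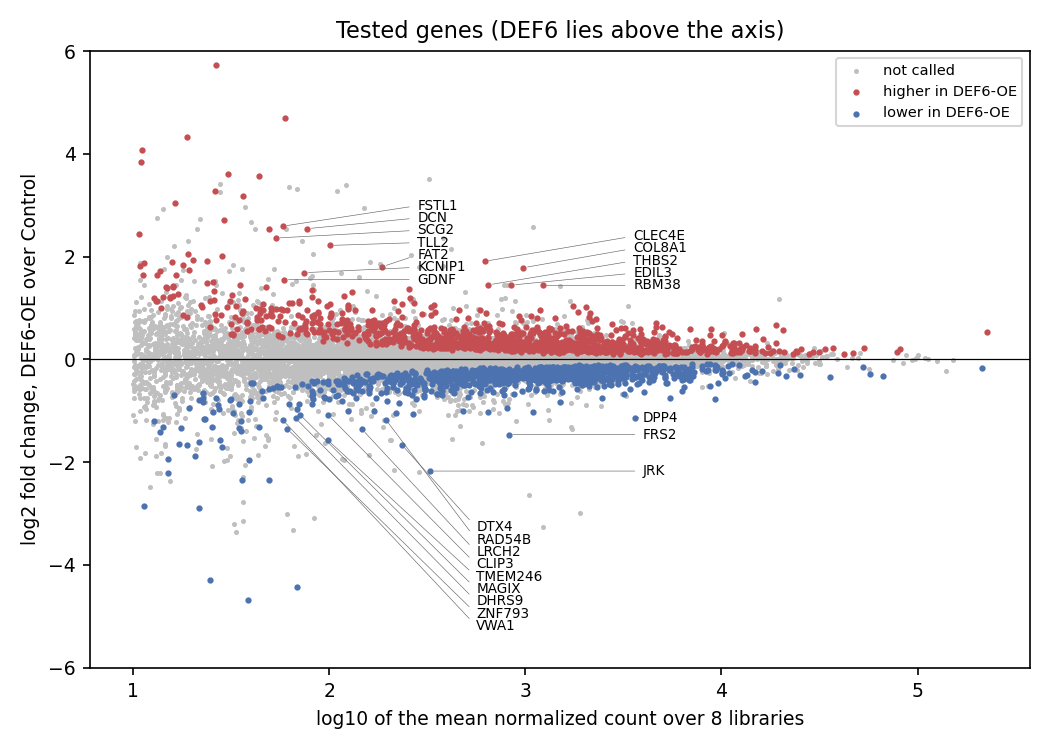
Log2 fold change of each tested gene against the log10 of its mean normalized count over the 8 libraries, with called genes in red (higher in DEF6-OE) and blue (lower) and the 24 genes named by rule (mean of at least 50, groups that do not overlap) labelled. DEF6, at 11.69, lies outside the axis, FSTL1 is at 2.59 and JRK at -2.18.

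Inflammatory genes of the NF-kB pathway were higher in DEF6-OE cells. Of 20 tested members of the list, 12 rose and none fell (15 rose when adjusted over the list alone). CCL20, a chemokine of lymphocytes and dendritic cells (chromosome 2, 227805739 to 227817564), rose from 143 ± 28.8 to 366 ± 14.7 normalized counts, a log2 fold change of 1.37 ± 0.13 (SE, limma adjusted p = 0.000797). TRAF1, an adaptor of tumour necrosis factor receptors, rose by 0.79 ± 0.06 and the adhesion molecule ICAM1 by 0.63 ± 0.05 (SE). IL6 and CXCL8 rose by 0.62 and 0.59, and the pathway's own subunits RELB, NFKB2 and NFKB1 by 0.47, 0.38 and 0.26. CCL2 rose by 1.92 from only 8.95 ± 5.38 normalized counts (1.17 with a pseudocount of 10), and its call held only without Control replicate 1 or 4 when libraries were left out in turn (adjusted p otherwise up to 0.0899). The list passed camera (adjusted p = 3.01e-08), with adjusted p = 0.235 with an estimated correlation.

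Matrix and mesenchymal genes were higher as well. In the list of TGF-beta targets and matrix, 11 of 20 tested members rose and none fell (11 rose and 1 fell when adjusted over the list alone). TGFBI, a matrix protein induced by TGF-beta, rose from 14669 ± 496 to 23335 ± 1064 normalized counts, a log2 fold change of 0.67 ± 0.04 (SE, limma adjusted p = 0.000122). TGFB2, the cross-linking enzyme gene LOXL2 and fibronectin, FN1, rose by 0.61, 0.57 and 0.53. FN1 reached 267505 ± 21758 normalized counts. In the list of fibroblast markers, 5 of 8 tested members rose and none fell (5 when adjusted over the list alone): COL3A1, DCN, LUM, TAGLN and FBN1. LUM rose from 157 ± 3.32 to 362 ± 48.4, FBN1 from 1523 ± 40.4 to 2683 ± 86.9 and TAGLN, which is in both lists, from 1357 ± 85.4 to 2741 ± 90.5. TAGLN lost its call in the FPKM table, at a log2 fold change of 0.58 against 1.02 (adjusted p = 0.111). COL3A1 had 84 reads in DEF6-OE and 3 in Control, a ratio of 29.2 with a 95% counting interval from 9.66 to 144. COL1A1, in contrast, had 235 ± 23.5 and 219 ± 12.3 normalized counts and was not called (adjusted p = 0.499). Camera gave an adjusted p of 6.67e-07 for the TGF-beta list and 2.07e-05 for the fibroblast list, with adjusted p = 0.0902 and 0.0732 with an estimated correlation.

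Mitotic genes were higher in DEF6-OE. Of 23 members of the mitosis list, 12 rose and none fell (13 rose when adjusted over the list alone). KIF20A, a kinesin of cytokinesis, rose from 311 ± 31.3 to 606 ± 16.7 normalized counts, a log2 fold change of 0.97 ± 0.08 (SE, limma adjusted p = 0.000411). Cyclin A2, CCNA2, rose by 0.66, UBE2C by 0.58, PLK1 by 0.54 and CCNB1 by 0.45, although UBE2C and PLK1 lost their calls in the FPKM table, at 0.48 and 0.37 (adjusted p = 0.0736 and 0.205). The list passed camera (adjusted p = 1.55e-08), with adjusted p = 0.235 with an estimated correlation. In the list of DNA replication genes 4 of 22 rose and none fell, led by TYMS at 0.25, and it did not pass (adjusted p = 0.306; 5 rose and 1 fell when adjusted over the list alone).

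A minority of the genes of the ATF4 stress response and of cholesterol synthesis was called, by small amounts. In the ATF4 list 8 of 22 members rose and none fell (10 when adjusted over the list alone). STC2, a secreted glycoprotein, rose by 0.71 ± 0.04 (SE, limma adjusted p = 5.48e-05), the serine synthesis enzyme PHGDH by 0.42 and ATF5 by 0.35. NUPR1 rose by 0.60, against 1.92 in the FPKM table (adjusted p = 0.0269), a call kept only without Control replicate 2 when libraries were left out in turn (adjusted p otherwise up to 0.104). In the cholesterol list 6 of 21 members fell and none rose (7 fell and 1 rose when adjusted over the list alone). HMGCS1, at -0.36 ± 0.06, and SQLE, at -0.27 ± 0.03 (SE), were among them, and CYP51A1, at -0.29, lost its call in the FPKM table, at -0.31 (adjusted p = 0.0866). ATF4 itself had 4472 ± 114 and 4472 ± 58.7 normalized counts. The camera adjusted p was 0.00048 for the ATF4 list and 0.0397 for the cholesterol list, with adjusted p = 0.0732 and 0.235 with an estimated correlation. The cholesterol call was lost without DEF6-OE replicate 1 (adjusted p = 0.0569) and without Control replicate 3 (adjusted p = 0.0759).

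The other 24 lists tested did not pass camera, although several held called members. Hypoxia-inducible factor targets had 6 higher and 1 lower of 25 (10 and 1 adjusted over the list alone, camera adjusted p = 0.138), with CA9 at 0.61 and VEGFA at 0.28. The p53 targets had 4 higher and 2 lower of 19 (5 and 2 adjusted over the list alone, adjusted p = 0.2), with POLH at 0.44. Interferon-stimulated genes had 5 higher and 2 lower of 22 (5 and 3 adjusted over the list alone, adjusted p = 0.224), with IFI6 at 0.74 and IFIT5 at -0.40. Tubular injury markers had 4 higher and 1 lower of 19 (5 and 1 adjusted over the list alone, adjusted p = 0.0736), with IGFBP7 at 0.49 and KRT19 at 0.29, and the list passed without Control replicate 2 (adjusted p = 0.0463). Proximal tubule genes had 3 higher of 9 (3 adjusted over the list alone, adjusted p = 0.138), with ASS1 at 0.22. Leukocyte markers had 3 higher and 1 lower of 6 (the same numbers adjusted over the list alone, adjusted p = 0.0736), with LCP1 at 0.97, CSF1R at 0.59 and CD68 at -0.47. CA9, VEGFA and CD68 lost their calls without at least 4 of the 8 libraries in turn (adjusted p up to 0.0701, 0.0638 and 0.07). In the FPKM table CA9, VEGFA, ASS1 and CSF1R had log2 fold changes of 0.49, 0.34, 0.41 and 0.56 but lost their calls (adjusted p = 0.0848, 0.0888, 0.14 and 0.109).

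A few genes related to WWP2 and PARP1 were called, where 16.4% of all tested genes were called, and none of their lists passed camera. In the NEDD4 family of ubiquitin ligases, to which WWP2 belongs, WWP1 fell by 0.41 ± 0.07 (SE, limma adjusted p = 0.00828) and NEDD4L rose by 0.49, the 2 called of 8 tested (the same numbers adjusted over the list alone, camera adjusted p = 0.862). In the PARP list PARP3 at 0.56 and NMNAT1 at 0.21 were higher and PARG, which removes poly(ADP-ribose), was lower at -0.32, of 23 tested (the same numbers adjusted over the list alone, adjusted p = 0.688). None of the 23 DNA strand break and base excision repair genes was called by limma, over all genes or adjusted over the list alone (camera adjusted p = 0.558). In the FPKM table NEDD4L, PARP3 and NMNAT1 had log2 fold changes of 0.16, 0.40 and 0.16 and lost their calls (adjusted p = 0.595, 0.0593 and 0.263), while PARG was at -0.52 (adjusted p = 0.0206). NEDD4L lost its call without 6 of the 8 libraries in turn and PARG without 5 (adjusted p up to 0.109 and 0.0801).

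Lists of cell death and stress genes did not pass camera either. Pro-apoptotic genes had 4 higher of 20 (5 adjusted over the list alone, camera adjusted p = 0.165), with BBC3 at 0.76, and anti-apoptotic genes 1 higher of 10 (1 adjusted over the list alone, adjusted p = 0.625), BCL2A1 at 0.98. Ferroptosis regulators had 1 higher and 4 lower of 18 (3 and 4 adjusted over the list alone, adjusted p = 0.709), with ACSL4 at -0.34. Pyroptosis and necroptosis genes had 2 higher and 1 lower of 10 (3 and 1 adjusted over the list alone, adjusted p = 0.622), with IL18 at -0.47. NRF2 targets had 4 higher and 1 lower of 20 (6 and 2 adjusted over the list alone, adjusted p = 0.138), with TXN at 0.47 and HMOX1 at 0.33. Endoplasmic reticulum chaperones had 3 higher and 1 lower of 19 (3 and 1 adjusted over the list alone, adjusted p = 0.625), with HYOU1 at 0.59 and PDIA4 at -0.31. Heat shock genes had 2 lower of 15 (1 higher and 2 lower adjusted over the list alone, adjusted p = 0.224), HSP90AA1 at -0.33 and HSPD1 at -0.34. In the FPKM table BBC3, IL18 and HMOX1 had log2 fold changes of 0.61, -0.40 and 0.27 but lost their calls (adjusted p = 0.0604, 0.0874 and 0.0746), while HSPD1 was at -0.57 there (0.0303). Quantile normalization ended the call of HSP90AA1, at -0.19 (adjusted p = 0.233). TXN and HMOX1 lost their calls without 5 of the 8 libraries in turn (adjusted p up to 0.0747 and 0.0639), and IL18 without Control replicate 4 (0.0518).

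Immediate-early genes had 4 higher and 2 lower of 20 (5 and 4 adjusted over the list alone, camera adjusted p = 0.301), with FOS at 0.56 and DUSP5 at -0.41. YAP/TAZ targets had 3 higher and 1 lower of 18 (5 and 3 adjusted over the list alone, adjusted p = 0.648), with CTGF at 0.37 and DLC1 at -0.49, a call lost in the FPKM table at -0.52 (adjusted p = 0.0684). Autophagy genes had 3 higher and 1 lower of 19 (5 and 2 adjusted over the list alone, adjusted p = 0.412), with LAMP1 at 0.48. Nuclear oxidative phosphorylation genes had 2 higher and 1 lower of 26 (0 adjusted over the list alone, adjusted p = 0.412). Ribosomal protein genes had 3 higher of 24 (6 adjusted over the list alone, adjusted p = 0.104), with RPL3 at 0.20, a call lost with quantile normalization at 0.12 (adjusted p = 0.098), and the list passed without DEF6-OE replicate 3 or 4 (0.0201 and 0.0206). Mitochondrially encoded genes had 3 lower of 13 (4 adjusted over the list alone, adjusted p = 0.0687), with MT-ND4L at -0.25, and passed in 8 alternatives. These were quantile normalization (adjusted p = 0.0122), the FPKM table (0.0263), no filter (0.0484) and equal totals (0.0486). The others left out DEF6-OE replicate 3 (0.0162), DEF6-OE replicate 4 (0.0206), Control replicate 1 (0.0476) or Control replicate 4 (0.0381). All 8 kept the preset correlation of 0.01. The estimated correlation was 0.49 for mitochondrially encoded and 0.41 for ribosomal protein genes, and with it neither list passed (camera adjusted p = 0.582 and 0.663). Distal nephron and endothelial markers had only 3 tested members each, with none called (0 for distal nephron and 1 higher and 1 lower for endothelial markers adjusted over the list alone), and were not tested as lists.

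**Figure D3:**
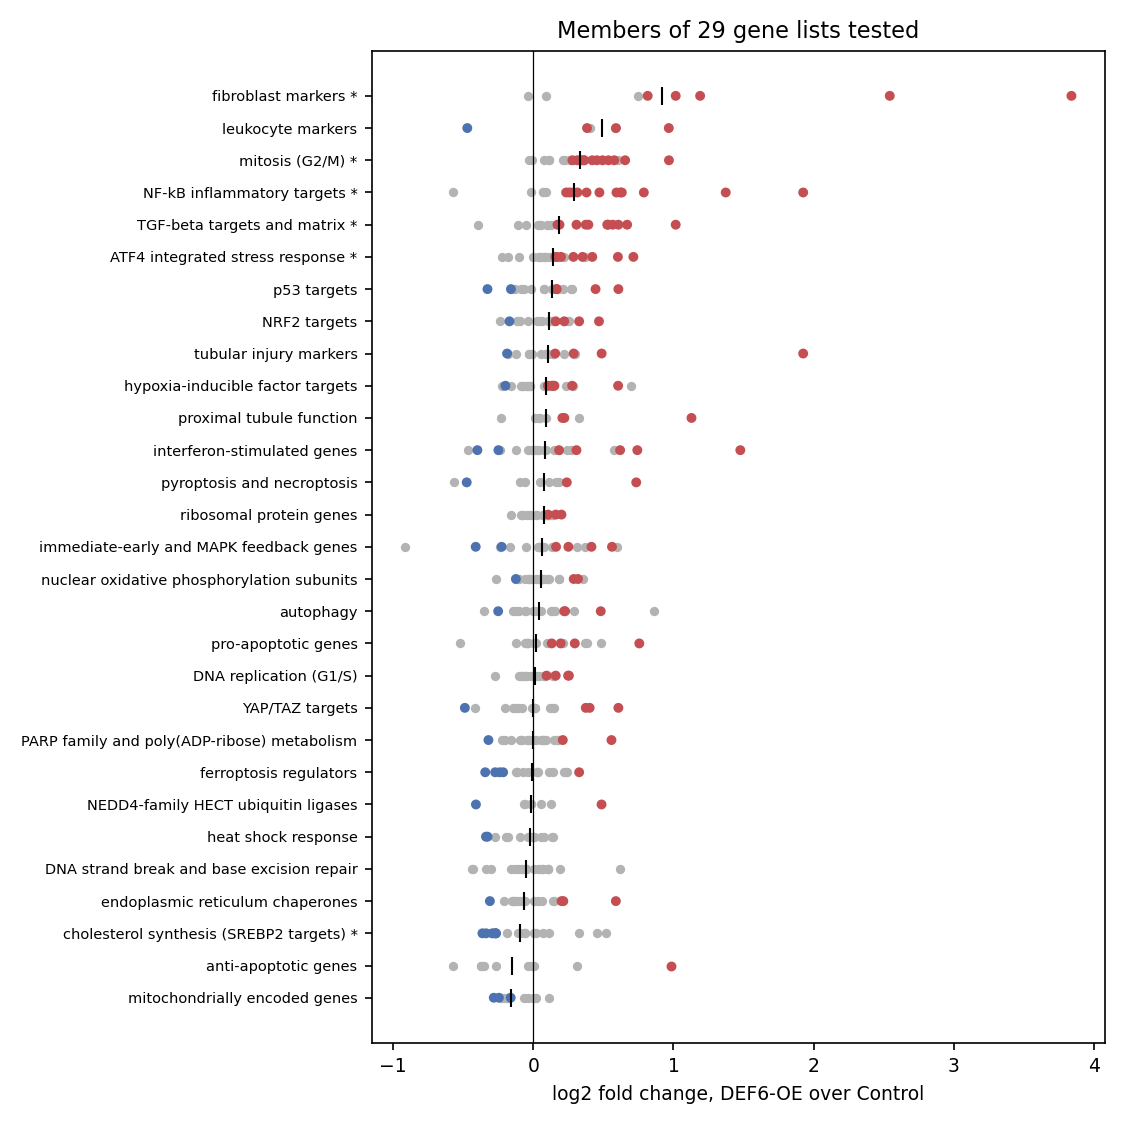
Log2 fold change (DEF6-OE over Control) of each tested member of 29 lists, in red or blue where called and grey where not, with the list median as a bar and an asterisk on the 6 lists past camera. Fibroblast markers have the highest median, 0.92, and mitochondrially encoded genes the lowest, -0.16.

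**Figure D4:**
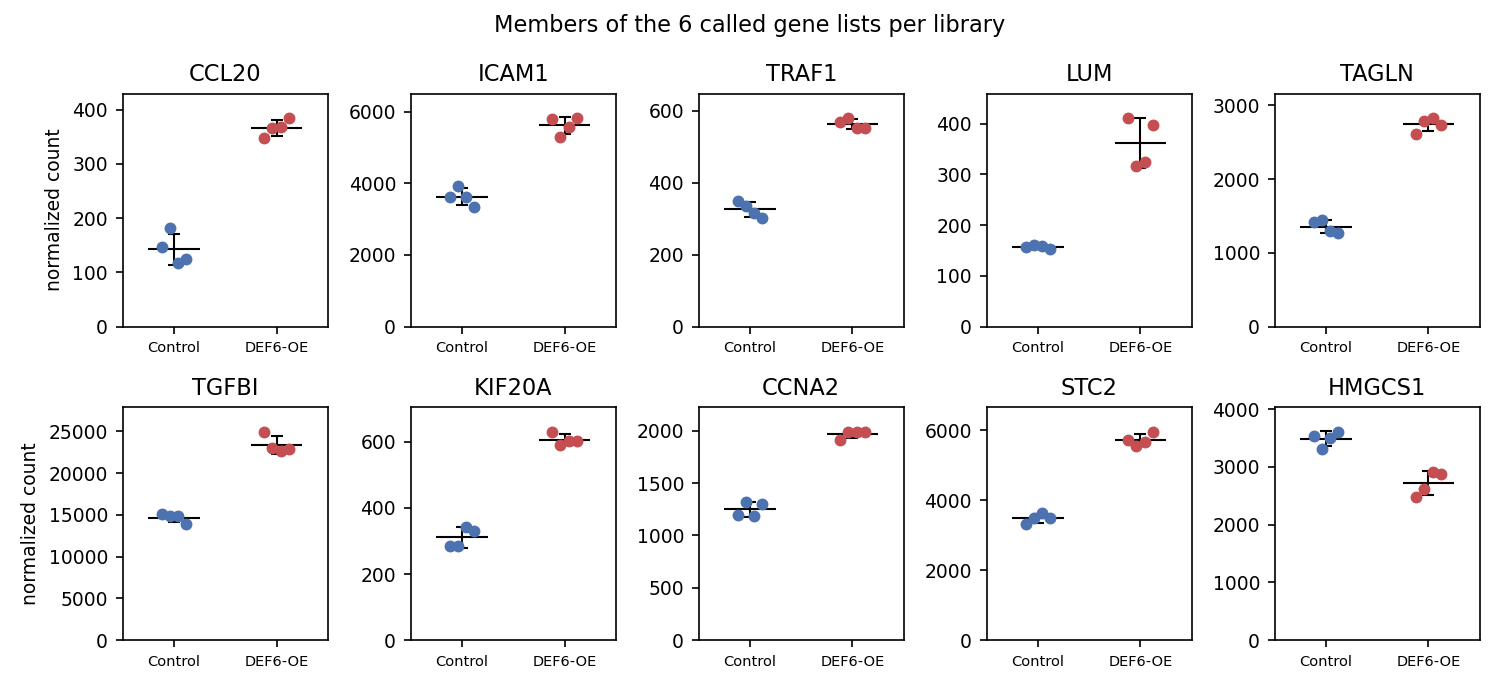
Normalized counts per library (linear axes from 0, group mean and SD) of 10 members of the 6 called lists. All 10 are called genes, and their groups do not overlap, which also holds for 2122 of the 2160 called genes. CCL20 is at 366 in DEF6-OE against 143 in Control, and HMGCS1 is lower in DEF6-OE, at 2720 against 3492.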

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

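The tests of overlapping genes and of the count to FPKM ratio in this part were chosen only after the result was seen. Of 252 groups of 4 libraries examined, 20 (7.94%) held a library farther from the other 3 than the critical value of Dixon's test, where chance gives about 1 in 20 groups.

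Among genes lower in DEF6-OE, DTX4 was at 248 normalized counts in DEF6-OE replicate 3 and at 75.6 to 87.8 in the other 3. FRS2 was at 1008 in DEF6-OE replicate 4 against 248 to 375, and RAD54B at 438 in Control replicate 2 against 199 to 225. WWP1 was at 1769 in Control replicate 4, CD68 at 2805 in Control replicate 3, HSPD1 at 37002 in Control replicate 2 and SQLE at 2611 in DEF6-OE replicate 1. Among genes higher in DEF6-OE, RBM38 was at 1491 in Control replicate 3 against 449 to 492 in the other 3, and SCG2 at 31.4 in Control replicate 4 against 14.6 or less. COL3A1 was at 3.00 in Control replicate 3, where the other 3 Control libraries were at 0, and at 39.4 in DEF6-OE replicate 3. PHLDA3 was at 1970, TXN at 10605 and VEGFA at 2658 in Control replicate 3. UBE2C was at 3343 in DEF6-OE replicate 2, and CCNA2 at 1917, CD74 at 1164 and TGFBI at 24914 in DEF6-OE replicate 1. WWP2, which was not called, was at 1394 in DEF6-OE replicate 2 against 989 to 1032. The number of genes above 0 was 14503 in DEF6-OE replicate 1 and 14637 to 14659 in the other 3.

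Some genes jumped in a single library, 411 times in 358 genes, with 79 jumps in DEF6-OE replicate 1 and 34 to 57 in each of the other libraries. MYC, for example, was at 312 normalized counts in DEF6-OE replicate 1 and at 2437 to 2673 in the other 3. Simulated counts held 96 jumps, but were drawn at the trend of the dispersion and not at each gene's own dispersion. Genes more variable than the trend are missing from them, so 411 against 96 does not measure an excess over ordinary variability. In some jumps an overlapping gene moved the other way by 0.5 to 2 times as much, as between EEF1G and AP002990.1. Of 404 placed jumps, 163 had a counted gene that overlaps in GENCODE 29, and 40 had such a partner (9.90% of the 404, 95% interval 7.17 to 13.2). Most jumps thus had no partner among the counted genes. Genes without counts, or overlapping only in the authors' annotation, could not be seen, so reads moved to or from those stay possible. A change of the estimated transcript mix of the gene could be involved: the count to FPKM ratio shifted in 77.4% of 402 jumps, against 44.6% for the same genes in the group without a jump, and this leaves it open. Among genes changed at least 2-fold, the ratio shifted between groups in 37 of 105 (35.2%, 95% interval 26.2 to 45.2), against 13.6% of 12801 genes, so a part of these changes may also rest on the estimated mix, which cannot be told apart from a change of the gene itself without the reads. No biological explanation of the jumps was tested.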

How the results depend on the processing

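The alternative restricted to genes with a stable count to FPKM ratio was chosen only after the result was seen. The 2160 called genes became 946 in the FPKM table and 1346 to 1939 with each library left out, lowest without DEF6-OE replicate 2, and were 2126 with edgeR, 2693 with DESeq2 and 2202 with equal totals, which gave 1079 higher and 1123 lower. The 138 genes changed at least 2-fold became 83 with a pseudocount of 10, 56 at a minimum mean of 50, 61 in the FPKM table, 57 with a stable ratio and 105 to 131 with each library left out. A larger pseudocount shrinks the changes of low genes, and the higher minimum and the stable ratio test fewer genes (11735 and 9077). For the FPKM table the cause was not tested. The 6 called lists became 0 with an estimated correlation and 18 with fry, which asks another question, and 5 to 8 with each library left out. All 6 were among the 18 (fry adjusted p = 1.46e-06 to 0.00142). The other 12 had not passed camera, leukocyte markers (fry adjusted p = 0.00106) and interferon-stimulated genes (0.00175) among them. The cholesterol list was also lost with neither trend nor robust (adjusted p = 0.064). DEF6 stayed between 10.02 and 12.08 on the log2 scale in the 20 alternatives that gave it a value, and the stable-ratio alternative gave none for DEF6 or WWP2. Of the 122 other called genes named by the rule, 53 passed the threshold in every alternative that tested them and 69 were lost or reversed in at least 1, among them 47 lost in the FPKM table. CALR alone reversed, from 0.21 to -0.03 in the FPKM table (adjusted p = 0.858), and the cause was not tested.

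With the replicate number as a block, 1004 genes were called, 93 of them changed at least 2-fold, and the cholesterol list was lost (adjusted p = 0.0523). The numbers did not pair the libraries: same-numbered libraries correlated at -0.028, -0.027, -0.031 and 0.018, and 0 of 4 correlated best with their own number. At this depth a Control count of 3 reads, as for COL3A1, leaves a ratio uncertain from 9.66 to 144.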

Other observations

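The gene families here, and the tests of contaminating cells and of the cell cycle, were chosen only after the result was seen. Chemokine and histone genes passed camera as higher in DEF6-OE and zinc finger genes of the ZNF series as lower, none of them with an estimated correlation. Of 8 chemokine genes tested 5 rose and none fell, among them CXCL5 by 0.31 ± 0.03 and CXCL16 by 0.50 ± 0.11 (log2, SE, n = 4 per group; camera adjusted p = 0.000889, adjusted p = 0.189 with an estimated correlation). Of the 5, CXCL5, CXCL8, CCL20 and CCL2 are members of the NF-kB list, so only CXCL16 adds to it. Of 33 histone genes 5 rose and none fell, led by H1FX at 0.53 ± 0.07 (camera adjusted p = 0.00169, adjusted p = 0.189 with an estimated correlation). Of 463 ZNF genes 26 fell and 5 rose, a smaller share lower than the 1008 of 13158 among all genes tested, and the family median was -0.11, with ZNF595 at -0.61 and ZNF680 at -0.67 (camera adjusted p = 0.0084, adjusted p = 0.283 with an estimated correlation). The medians of the chemokine, histone and ZNF families kept their sign with equal totals, quantile normalization and the FPKM table. Collagens went both ways, 8 higher and 4 lower of 22 (camera adjusted p = 0.146). COL6A3, at 3.18, and COL22A1, at -4.29, had low counts. In DEF6-OE they were at 66.3 ± 4.35 and 2.46 ± 2.93 normalized counts, and in Control at 6.71 ± 2.44 and 47.1 ± 9.80 (SD). Keratin, kinesin, integrin, solute carrier, protocadherin, matrix metalloproteinase and tRNA synthetase genes did not pass (camera adjusted p = 0.0679, 0.426, 0.82, 0.746, 0.236, 0.223 and 0.876). Keratin genes passed when only the 7 with a stable count to FPKM ratio were kept (camera adjusted p = 0.0091, preset correlation). The estimated correlation was run only on all 11 keratin genes, which did not pass with it (camera adjusted p = 0.189).

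The real grouping stood apart from the other splits in its gene counts but not in its count of lists. Of the 35 splits of the 8 libraries into 4 and 4, only 1, the real one, gave as many called genes (2160, highest other split 6) or as many genes changed at least 2-fold (138, highest other 4). That is the best rank that 35 splits allow. The other splits mix the groups, so the group difference widens the spread within them and holds their calls down. This comparison therefore does not exclude chance for the gene counts. As many called lists as the real 6 came from 7 of the 35 splits, with up to 8, so chance is not excluded for the number of lists. The other 6 of these splits kept 3 libraries of each group together and so hold a part of the real contrast, while the 18 splits with 2 and 2 of each group gave at most 4 lists, and 0 in 12 of them. For the NF-kB, TGF-beta, fibroblast, ATF4 and cholesterol lists only 1 of the 35 splits, the real one, gave a p as small, and for the mitosis list 3 did. A count of 1 is the smallest possible here, and these lists were picked by their p in the real split. The counts were not adjusted over the 30 lists tested, so they add no support for single lists.

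A candidate explanation of the higher fibroblast and matrix genes is fibroblasts mixed into the DEF6-OE cultures. COL1A1, an abundant fibroblast transcript, gained 15.4 normalized counts (95% interval -17.2 to 47.9), less than LUM at 205 (146 to 264). Taken alone this argues against it, but it rests on a single gene, and COL1A2 was listed at 0 FPKM in all 8 libraries. The marker genes THY1 and PDGFRB, at low counts, gained 4.45 (-6.47 to 15.4) and 5.47 (-2.78 to 13.7), so the question is not settled. COL6A1 and COL6A2 differed by -276 (-618 to 66.0) and 181 (-460 to 823) normalized counts. SPARC gained 2636 (1894 to 3377), TAGLN 1385 (1232 to 1537) and FBN1 1159 (1042 to 1277). DCN gained 106 (86.8 to 125) and COL6A3 59.6 (53.5 to 65.7). A difference between the derived DEF6-OE cells and the wild-type cells other than DEF6, such as clonal drift, stays open and untested. That holds for all called genes and lists, not only for the fibroblast and matrix genes.

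A larger share of cells late in the cell cycle was considered for the higher mitosis genes and stays open. The mean of the mitosis list minus that of the DNA replication list was 0.32 higher in DEF6-OE (log2), but this restates the list values that raised the question and adds no support. No cell counts or cycle measurements were used.

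CXCL1, a chemokine gene, was listed at 0 in 7 of the 8 libraries and at 9.93 normalized counts in Control replicate 1, and COL1A2 was listed at 0 FPKM in all 8.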
